A study of Mus musculus with 38 samples.

How the data were processed

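RNA was measured by bulk sequencing in 38 libraries from mouse lung adenocarcinoma organoids, which are clusters of tumour cells grown in a gel matrix. Each organoid line came from 1 tumour and carried a tamoxifen-activated Cre recombinase together with floxed Foxa1, floxed Foxa2 or both. Cultures received ethanol vehicle or 2 uM 4-hydroxytamoxifen (4-OHT) for 72 hours. The labels also mention 21 days after treatment, but for crosslinked cells, so the time at which RNA was collected is not given in the sources used here. RNA was isolated with a column kit and libraries were made with a directional kit.

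The deposited tables hold raw read counts per Ensembl gene ID for each library, with no normalisation. Whole numbers with totals that differ between libraries were found in all 3 tables when checked. The authors' processing notes name GRCm38, STAR 2.7.6a, featureCounts 1.5.1 and DESeq2, without saying which step each served. The strand setting of the counting, its treatment of reads that map to several places and the annotation release are not given in the sources used here. Values of genes with close paralogs (the Prl2c, Mcpt, Tpsab1, Ctla2a, Sprr, Oas, Ugt2b and H2 genes, and the neighbouring Myh6 and Myh7) are therefore uncertain as to which copy the reads came from. Total counts (M, mega) ran from 18.3 to 32.0 M in the double-floxed table, 18.5 to 33.2 M in the single-floxed table and 13.6 to 16.3 M in the hairpin table. The tables list 55421 IDs (double-floxed) and 55487 IDs (the other two), and 99.5% and 99.4% of these had a gene symbol in the annotation.

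Groups came from the genotype, treatment and hairpin in the labels. There were 5 vehicle and 5 4-OHT libraries with both genes floxed (3 lines), 6 and 6 with Foxa1 floxed (3 lines), and 4 and 4 with Foxa2 floxed (2 lines). A further experiment had 2 libraries in each of 4 groups made from 1 double-floxed line with a scrambled hairpin (shScramble) or a hairpin against Nkx2-1 (shNKX2-1). Repeat libraries of a line are not independent tumours, and the labels do not say whether the 2 libraries of a hairpin group came from separate cultures. Pairing by line was checked on centred log2 values. Vehicle and 4-OHT libraries of a line correlated with r from 0.157 to 0.774 in double-floxed, 0.439 to 0.877 in Foxa1-floxed and 0.553 to 0.862 in Foxa2-floxed organoids. All pairs from different lines of a genotype had negative r, but centring over 2 or 3 lines largely sets that sign in advance.

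Changed genes were called in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM normalisation, quasi-likelihood F test), at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Organoid line was a block in the double-floxed and single-floxed fits, with line as the replicate block and the 2 single-floxed genotypes fitted together. The comparisons of effects between genotypes used counts summed per line and treatment, since genotype differs between lines. The hairpin fit had 4 group means and 1 shared estimate of the spread. Expression levels are counts per M counts (CPM) scaled by the TMM factors, given as mean ± SD over libraries. A prior count of 2 was added for log2 CPM in the list tests. Where a group had 0 counts, the fold is a lower bound from a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with a 95% exact counting interval. Floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

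Before the data were examined, 24 gene lists, the comparisons, the alternatives and the genes to be named were fixed. Named were the 12 genes per direction with the largest fitted change among called genes in the double-floxed comparison (8 in the others, 6 for differences between effects), with mean log2 CPM of at least 2 and the same sign in every line or library. Foxa1, Foxa2, Foxa3, Nkx2-1 and up to 4 members per list with the smallest adjusted p (2 in the other direction) were also named. Lists were tested with limma 3.58.1 (camera, preset correlation 0.01) and again with the correlation estimated from the data, adjusted over the 21 to 24 lists with at least 3 measured members. The lists described are alveolar type 2, alveolar type 1, gastric and intestinal, squamous and basal, embryonic lung tip, airway secretory, ciliated, neuroendocrine, transitional alveolar, mesenchymal transition, epithelial junction, cell cycle, MAPK feedback, YAP and TEAD targets, Wnt targets, interferon response, antigen presentation, lipid synthesis, hypoxia and glycolysis, unfolded protein response, and NF-kB and chemokine genes, with 3 lists of other cell types (fibroblast, endothelial and leukocyte). Among all 10 comparisons, the preset-correlation call of 1 list also passed with an estimated correlation, that of the leukocyte list in Foxa2-floxed organoids.

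Alternatives were RLE normalisation, DESeq2 1.42.0, no filter on low counts, a minimum log2 change of 1, no replicate block, a block of line and run, counts summed per line, each genotype fitted alone, libraries as units in the comparisons of effects, and leaving out each line or library. Calling was tested on simulated data built from the libraries. Planted 4-fold changes were recovered for 59.4% of genes in the double-floxed design, 85.4% in the Foxa1-floxed, 76.8% in the Foxa2-floxed, 48.0% and 66.3% in the comparisons of effects (double against single, Foxa1 against Foxa2), 54.8% to 68.0% in the 4 hairpin contrasts and 19.2% in the hairpin interaction. Planted 2-fold changes were recovered for 8.51%, 65.7%, 50.5%, 10.3%, 16.0%, 2.04% to 5.15% and 1.05%, in the same order. False calls made up 2.98% of calls in the double-floxed design, 14.9% in the comparison of Foxa1 with Foxa2 effects and at most 12.3% in the others. The simulated libraries were independent, with the same change planted in every line of a genotype. These rates leave out tumours that respond differently and dependence between repeat libraries, so they can be too favourable. No library was left out.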

Results

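RNA was sequenced from organoids of 8 mouse lung adenocarcinomas that express Nkx2-1, the lung lineage transcription factor, and that can be made to lose the forkhead factors Foxa1 and Foxa2. The series comprised 38 libraries. Treatment with 4-OHT switches on Cre, which excises floxed sequence, so each line supplied its own vehicle control. Double-floxed organoids gave 5 vehicle and 5 4-OHT libraries from lines 1027B (replicates 1 and 4), 1027D (replicates 2 and 5) and 1292B (replicate 3). Foxa1-floxed organoids gave 6 and 6 from lines 1552A, 1552B and 1552C, with 2 consecutive replicates each. Foxa2-floxed organoids gave 4 and 4 from lines 1267B (replicates 1 and 2) and 1526C (replicates 3 and 4). A further experiment in line 1027B combined a scrambled or an Nkx2-1 hairpin with vehicle or 4-OHT, with 2 libraries per group. Total counts were 18.3 to 32.0 M per double-floxed library, 18.5 to 33.2 M per single-floxed library and 13.6 to 16.3 M per hairpin library. Mitochondrial transcripts took 1.09% to 4.30% of the counts in 37 libraries and 11.7% in shNKX2-1 4-OHT replicate 2.

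The targeted genes lost expression as follows. Foxa2 (ENSMUSG00000037025, GRCm38 chromosome 2, 148042877 to 148046969) fell from 114 ± 47.7 to 4.89 ± 1.41 CPM in double-floxed organoids (mean ± SD, n = 5 and 5; adjusted p = 0.00151). It fell from 97.6 ± 22.7 to 2.83 ± 1.00 CPM in Foxa2-floxed organoids (n = 4 and 4; adjusted p = 3.55e-09). Foxa1 (ENSMUSG00000035451, chromosome 12, 57540628 to 57546916) fell from 47.7 ± 28.8 to 13 ± 3.40 CPM in double-floxed organoids (adjusted p = 0.0284). The decrease was from 59.8 ± 16.3 to 15.4 ± 1.24 CPM in Foxa1-floxed organoids (n = 6 and 6; adjusted p = 6.08e-07). The fall in Foxa1 was not uniform, since double-floxed vehicle replicate 1 held 17.4 CPM and the 4-OHT libraries held 9.10 to 18.4 CPM. In the single-floxed lines the other paralog did not pass the test: Foxa2 stood at 134 ± 49.8 and 139 ± 32.8 CPM in Foxa1-floxed organoids (adjusted p = 0.806). Foxa1 stood at 98.7 ± 23.2 and 142 ± 6.24 CPM in Foxa2-floxed organoids (adjusted p = 0.0644). Foxa3 (ENSMUSG00000040891, chromosome 7, 19013284 to 19023538), a related factor, stood at 24.6 ± 10.8 and 8.35 ± 4.5 CPM in double-floxed organoids (adjusted p = 0.0652). Foxa3 and Nkx2-1 were the only genes named for this comparison without a call. With a block of line and run, 1 of them was called. Nkx2-1 (ENSMUSG00000001496, chromosome 12, 56531958 to 56536908) stood at 209 ± 89.6 CPM with vehicle and 210 ± 81.5 CPM with 4-OHT in the double-floxed lines (adjusted p = 0.987). Nkx2-1 did not pass in the single-floxed lines either (adjusted p = 0.561 and 0.664 in Foxa1-floxed and Foxa2-floxed). These are counts over whole genes, and no exon-level values were at hand to show excision itself.

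**Figure D1:**
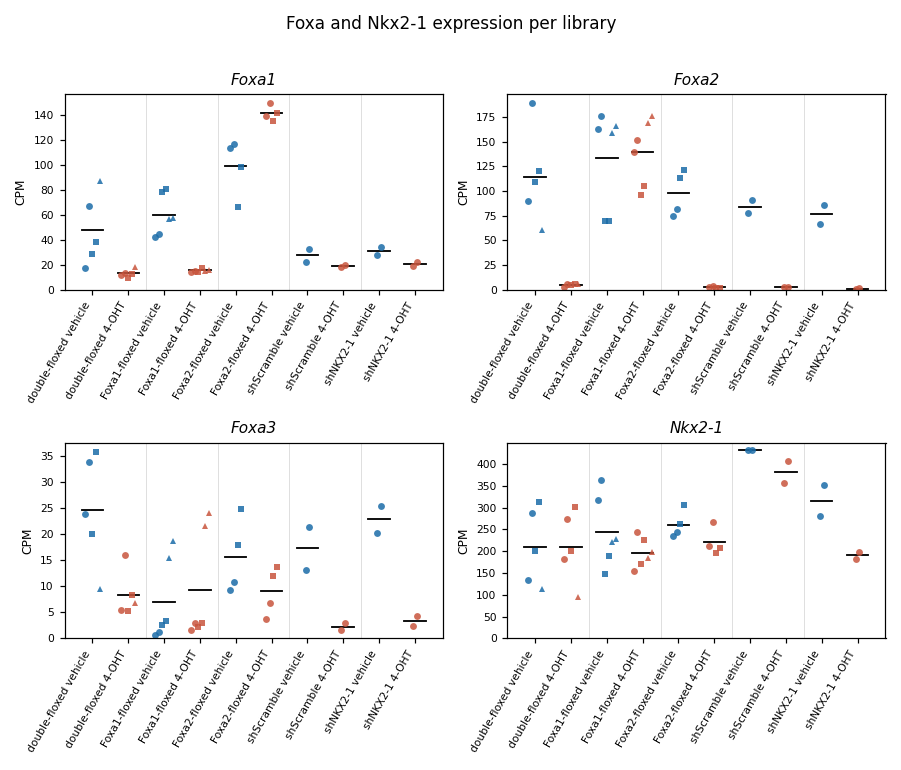
Expression (CPM, vertical axes) of Foxa1, Foxa2, Foxa3 and Nkx2-1 in each of the 38 libraries by group (horizontal axes), with vehicle in blue, 4-OHT in red, 1 marker shape per line within a genotype and black bars at the group means. Foxa2 lies at 0.315 to 6 CPM in the 4-OHT libraries of all lines with floxed Foxa2, and Foxa1 lies at 18.5 to 22.1 CPM in the 4-OHT libraries of the hairpin experiment.

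The double-floxed comparison asked which genes change with 4-OHT in Nkx2-1-positive tumour cells with both genes floxed. No line without floxed Foxa1 or Foxa2 was included. In each comparison of 4-OHT with vehicle, effects of 4-OHT or Cre themselves therefore cannot be told apart from those of gene loss. Trf, which encodes the iron carrier transferrin, fell from 1775 ± 1847 to 0.352 ± 0.457 CPM (adjusted p = 9.14e-04), with each of the 5 4-OHT libraries below every vehicle library. Gkn2, a gastrokine of the stomach lining, fell from 288 ± 229 to 0.402 ± 0.529 CPM, and Tff1, a trefoil peptide of gastric mucus, from 538 ± 694 to 0.876 ± 0.981 CPM (n = 5 and 5; adjusted p = 0.00491 and 0.0135). In the opposite direction, Krt14, a keratin of basal and squamous cells, rose from 3.32 ± 3.04 to 79.5 ± 83.9 CPM (adjusted p = 0.0123). Of 15198 genes tested, 302 were called higher and 290 lower with 4-OHT.

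Among the other genes with the largest decreases were Itih2, a serum protein that binds hyaluronan (58.3 ± 63.3 to 0.0306 ± 0.0284 CPM, adjusted p = 3.45e-04), and Myh7, a cardiac myosin heavy chain (141 ± 85.4 to 0.101 ± 0.110 CPM, adjusted p = 8.76e-04). Muc5b, an airway mucin, fell from 493 ± 201 to 5.42 ± 5.89 CPM (adjusted p = 0.00599). The pepsinogen gene Pgc fell from 38.9 ± 77.6 to 0.0683 ± 0.0816 CPM, with 177 CPM in vehicle replicate 1 alone (adjusted p = 0.0292). For Myh6, Serpind1 and R3hdml the 4-OHT libraries held 1, 1 and 2 counts together. Their ratios of 4-OHT to vehicle were 1.57e-05 to 0.00346 for Myh6, 2.66e-05 to 0.00588 for Serpind1 and 2.16e-04 to 0.00648 for R3hdml (95% counting intervals). The largest increases were in Rnf144a, a ubiquitin ligase (0.0356 ± 0.0797 to 10.9 ± 9.91 CPM, adjusted p = 0.0232), and the collagen gene Col6a1 (0.0356 ± 0.0797 to 9.33 ± 7.44 CPM, adjusted p = 0.00626). Prl2c3 of the prolactin family rose from 1.67 ± 2.78 to 299 ± 593 CPM, with 1359 CPM in replicate 3. Pglyrp3, an antibacterial protein of epithelia, rose from 0.157 ± 0.143 to 9.85 ± 7.66 CPM. Tpsab1, a mast cell tryptase, rose from 4.37 ± 5.85 to 217 ± 293 CPM (adjusted p = 0.0106). The genes Fgf15, Rsad2, Cpa4, Afap1l2, Lypd5 and Ctla2a were also among the 12 largest increases, at 34.7-fold to 49.9-fold.

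By gene group, 7 of 24 measured alveolar type 2 genes fell and 0 rose (9 lower when adjusted over the list alone). They included the surfactant gene Sftpa1 (166 ± 263 to 0.450 ± 0.693 CPM), the lung chemokine Cxcl15 (805 ± 937 to 7.08 ± 8.28 CPM), the complement gene Hc (16.6 ± 21.0 to 0.193 ± 0.204 CPM) and Cebpa, a transcription factor of alveolar and liver cells (148 ± 42.0 to 50.9 ± 17 CPM). Vehicle replicate 1 alone held 2473 CPM of Cxcl15, against 287 to 489 CPM in the other vehicle libraries. The vehicle libraries of line 1027B themselves differed in this list, with 22 of 24 genes lower in run 17992. The alveolar type 2 list was lower as a set (adjusted p = 2.96e-06), but not past the threshold with an estimated correlation (adjusted p = 0.396 with an estimated correlation). Of 21 gastric and intestinal genes, 6 fell and 0 rose, among them Gkn3 (24.1 ± 26.0 to 0.0298 ± 0.0422 CPM) and Vsig1 (52.2 ± 40.2 to 1.16 ± 2.35 CPM), with 1 higher and 12 lower when adjusted over the list alone (list adjusted p = 4.66e-09, and adjusted p = 0.144 with an estimated correlation). Of 20 squamous and basal genes, 3 rose and 0 fell (9 higher when adjusted over the list alone). These were Krt14, the cornified envelope gene Ivl (64.3 ± 40.8 to 248 ± 178 CPM, adjusted p = 0.0450) and the desmosome gene Pkp1 (6.73 ± 6.26 to 20.9 ± 14.7 CPM, adjusted p = 0.0112), with a list adjusted p = 0.00193, and adjusted p = 0.457 with an estimated correlation. Of 4 measured ciliated cell genes, Foxj1 and Tppp3 rose (0.132 ± 0.135 to 1.09 ± 0.933 and 2.05 ± 2.79 to 11.8 ± 20.5 CPM) and 4 were higher when adjusted over the list alone (list adjusted p = 1.97e-04, and adjusted p = 0.144 with an estimated correlation). Tppp3 was carried by replicate 3, from line 1292B, at 48.4 CPM. Of 22 interferon response genes, 1 was called, Rsad2, and 1 when adjusted over the list alone (list adjusted p = 2.27e-06 for higher values, and adjusted p = 0.457 with an estimated correlation). Csf1 and its receptor Csf1r, which act in macrophages, rose from 9.32 ± 13.1 to 77.7 ± 64.0 and from 0.446 ± 0.621 to 8.69 ± 10.6 CPM. The leukocyte list, whose only call was Csf1r, did not pass (adjusted p = 0.102), nor did the fibroblast and endothelial lists (adjusted p = 0.284 and 0.326).

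The edgeR counts rest on 3 tumours and on the block by line, and lines 1027B and 1027D share a line number. Counts summed per line gave 564 calls, and 346 of these shared the call and its sign with the reported 592. With a block of line and run 1783 genes were called, without a block 82, without line 1027B 111, and without line 1292B 253. Without line 1027D edgeR called 0 (1660 at an unadjusted p under 0.05), while DESeq2 called 1892 on all lines. Leaving out 1 library at a time gave 316, 228, 237, 319 and 368 calls without vehicle replicates 1 to 5, and 263, 235 and 277 without 4-OHT replicates 2, 3 and 5.

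**Figure D2:**
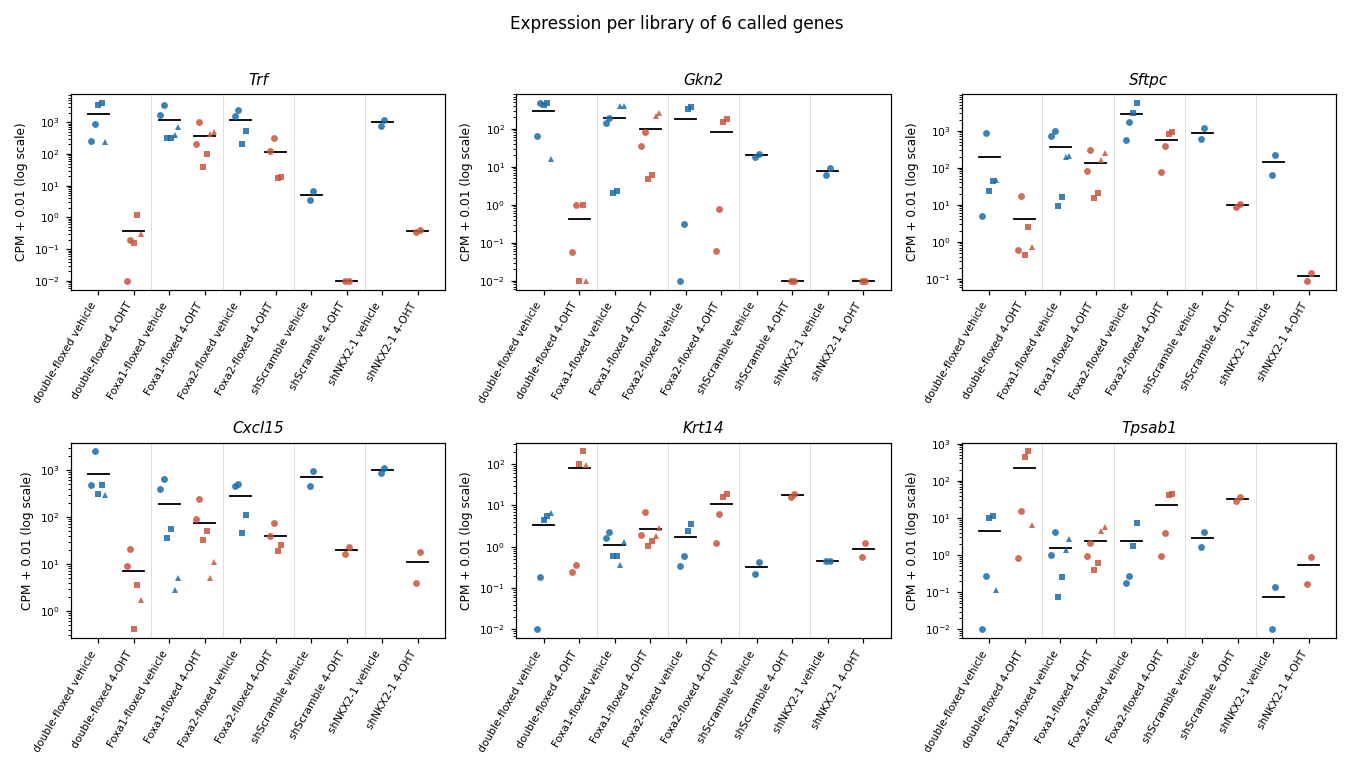
Expression (CPM plus 0.01, logarithmic vertical axes) of Trf, Gkn2, Sftpc, Cxcl15, Krt14 and Tpsab1 in each library by group (horizontal axes), with colours, markers and mean bars as for the target genes. Trf is at 0.352 CPM on average in double-floxed 4-OHT libraries against 119 CPM in Foxa2-floxed 4-OHT libraries, and Krt14 is at 17.7 CPM in shScramble and 0.890 CPM in shNKX2-1 libraries with 4-OHT.

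In Foxa1-floxed organoids, treated to remove Foxa1 alone, 2 of 16887 genes were called. Foxa1 itself fell by 1.92 on the log2 scale in 6 of 6 4-OHT libraries, and Tcp11l1, a gene of little known function, rose from 2.03 ± 0.798 to 6.03 ± 3.51 CPM (n = 6 and 6; adjusted p = 0.0298). No member of any list was called over all genes, although 1928 genes had an unadjusted p under 0.05 where chance gives 844. Of 26 alveolar type 2 genes, 25 had lower fitted values with 4-OHT, 1 was lower when adjusted over the list alone, and the list adjusted p was 5.28e-09 (adjusted p = 0.357 with an estimated correlation). Fitted values of the squamous and basal list were higher for 17 of 20 genes, with 3 higher when adjusted over the list alone (list adjusted p = 0.00172, and adjusted p = 0.357 with an estimated correlation). The lipid synthesis list had lower fitted values for 20 of 22 genes, with 0 called when adjusted over the list alone (list adjusted p = 2.32e-05, and adjusted p = 0.357 with an estimated correlation). Unlike in the other genotypes, the gastric and intestinal list had higher fitted values, for 18 of 25 genes, with 2 higher when adjusted over the list alone (list adjusted p = 0.0148, and adjusted p = 0.357 with an estimated correlation). Airway secretory genes were higher for 14 of 17 members (list adjusted p = 0.0200, and adjusted p = 0.357 with an estimated correlation) and interferon response genes for 20 of 22 (list adjusted p = 0.00815, and adjusted p = 0.619 with an estimated correlation). The transitional alveolar, cell cycle, YAP and TEAD target, and NF-kB and chemokine lists were also higher (adjusted p = 0.00238, 0.0121, 0.00172 and 0.00172, and adjusted p = 0.357, 0.692, 0.361 and 0.361 with an estimated correlation). Hypoxia and glycolysis and unfolded protein response lists were lower (adjusted p = 0.00208 and 0.00238, and adjusted p = 0.405 and 0.361 with an estimated correlation). DESeq2 called 246 genes and edgeR without the low-count filter 1141, while counts summed per line gave 0 calls (1516 at an unadjusted p under 0.05). Without line 1552B 21 genes were called, and without 1552A or 1552C 1 gene, as without the block.

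Foxa2-floxed organoids were treated to remove Foxa2 alone. Trf fell from 1184 ± 1006 to 119 ± 140 CPM (n = 4 and 4; adjusted p = 0.00165) and Itih2 from 14 ± 8.98 to 0.561 ± 0.482 CPM (adjusted p = 1.04e-06). Myh7 fell from 281 ± 95.4 to 22.4 ± 19.4 CPM (adjusted p = 6.62e-06, lower in 4 of 4 4-OHT libraries). Mast cell proteases rose: Mcpt1 from 1.43 ± 0.406 to 39.5 ± 31.9 CPM, Mcpt8 from 1.51 ± 0.862 to 20.2 ± 4.62 CPM and Tpsab1 from 2.37 ± 3.39 to 22.4 ± 23.1 CPM (adjusted p = 9.14e-04, 4.52e-04 and 0.00961). The other large increases were in Prl2c2 (0.972 ± 0.988 to 87.7 ± 101 CPM), the matrix genes Col8a1 and Fbln2 (0.0712 ± 0.0305 to 2.32 ± 1.28 and 1.97 ± 1.72 to 20.8 ± 8.39 CPM), Fam167a (3.42 ± 1.2 to 35.2 ± 5.92 CPM) and Irf7. Other large decreases were in Phf24, Gna14 and Myh6, at 14.5-fold to 20.6-fold. Cldn6 was called lower at few counts (1.26 ± 1.48 to 0.0939 ± 0.0919 CPM), but its log2 changes were -3.37 and -0.14 in the 2 lines, and 0 of 4 4-OHT libraries lay below every vehicle library. Of 16887 genes tested, 319 were called higher and 261 lower.

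In the same organoids 9 of 26 alveolar type 2 genes fell and 0 rose (14 lower when adjusted over the list alone), including the surfactant lipid enzyme Lpcat1 (286 ± 168 to 118 ± 64.6 CPM) and Cxcl15 (281 ± 237 to 39.7 ± 25.5 CPM), with a list adjusted p = 4.69e-08, and adjusted p = 0.273 with an estimated correlation. Of 25 gastric and intestinal genes, Tff1 (638 ± 661 to 109 ± 114 CPM), Agr2 (386 ± 566 to 58.8 ± 68.1 CPM) and Pgc (9.91 ± 10.9 to 2.92 ± 4.30 CPM) fell, with 1 higher and 6 lower when adjusted over the list alone (list adjusted p = 0.0169, and adjusted p = 0.317 with an estimated correlation). Of 20 squamous and basal genes, 5 rose and 1 fell (6 and 1 when adjusted over the list alone). Ivl rose from 16.8 ± 1.47 to 84.7 ± 15.8 CPM and Krt14 from 1.72 ± 1.55 to 10.6 ± 8.20 CPM. In contrast Krt4, a keratin of internal stratified epithelia, fell from 29.7 ± 26.9 to 7.80 ± 8.10 CPM (list adjusted p = 7.02e-05, and adjusted p = 0.273 with an estimated correlation). In the embryonic lung tip list, 4 of 17 genes fell, the signalling genes Shh and Bmp4 and the transcription factors Foxp2 and Etv5 (Shh from 8.67 ± 6.48 to 1.52 ± 0.677 CPM), with 2 higher and 4 lower when adjusted over the list alone (list adjusted p = 0.124). Interferon response genes had higher fitted values for 22 of 22 members, with 2 called, Irf7 and Zbp1, and 18 when adjusted over the list alone (list adjusted p = 1.88e-07, and adjusted p = 0.367 with an estimated correlation). Both calls leaned on replicate 2, where Irf7 reached 326 CPM against 7.84 to 56.0 CPM in the other 4-OHT libraries. The same library held 649 CPM of B2m, a subunit of MHC class I, which rose from 75.6 ± 64.6 to 243 ± 273 CPM as the only call of 10 antigen presentation genes (6 when adjusted over the list alone; list adjusted p = 1.05e-04, and adjusted p = 0.273 with an estimated correlation). The leukocyte list was higher with both correlations (adjusted p = 5.28e-04, and adjusted p = 0.0441 with an estimated correlation). Its calls were Csf1r (0.954 ± 0.769 to 4.34 ± 2.24 CPM) and the integrin gene Itgam (0.104 ± 0.0715 to 0.507 ± 0.205 CPM), 2 of 7 members and 2 when adjusted over the list alone. The fibroblast and endothelial lists did not pass (adjusted p = 0.232 and 0.462).

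The Foxa2-floxed count stands on 2 tumours, and the p-values of single genes above take repeat libraries of a line as units. With counts summed per line, 31 of the genes named for this comparison lost their call and 14 stayed on their side of the threshold. Without line 1526C, 38 lost their call. The count of changed genes was 580 in the reported fit. It was 73 with counts summed per line, 133 with this genotype fitted alone, 5 without the block, 914 with a block of line and run, 988 by DESeq2, 16 without line 1526C and 1059 without line 1267B. Without 4-OHT replicate 1 it was 927, without vehicle replicates 3 and 4 it was 252 and 234, and without 4-OHT replicates 3 and 4 it was 240 and 227.

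The genes called in double-floxed organoids were also followed in the single-floxed organoids. Of those tested in both, 77 of 270 called higher and 85 of 287 called lower in double-floxed organoids had the same call in Foxa2-floxed organoids, where chance gives 5.21 and 4.47, and 0 had the opposite call. As lists, the genes called higher lay higher and those called lower lay lower in Foxa2-floxed organoids (camera p = 7.57e-47 and 8.08e-48, and p = 2.09e-04 and 3.19e-05 with an estimated correlation). In Foxa1-floxed organoids the same lists lay in the same directions (p = 1.13e-14 and 8.20e-11, and p = 0.0173 and 0.0160 with an estimated correlation), with Foxa1 as the only shared call.

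Whether the effect of losing both genes differed from the mean effect of losing 1 was tested directly, over 8 lines. Lines 1552A, 1552B and 1552C share a line number, as do 1027B and 1027D, so the 8 may not be independent units. Since that mean includes the Foxa1-floxed lines, a gene that responds to Foxa2 alone can also pass. Double-floxed lines were not tested against Foxa2-floxed lines alone. Effects were more negative in double-floxed lines for Trf by -9.29, for the thyroxine carrier Ttr by -9.19, for Gkn2 by -8.96, for Gkn3 by -8.61, for the airway secretoglobin Scgb3a1 by -8.55 and for Myh6 by -8.31 (log2 difference of effects; adjusted p = 0.00310, 0.0134, 0.00555, 0.0214, 0.0437 and 0.00555). Scgb3a1 was not called in the double-floxed comparison itself, where Muc5b was the 1 call among 13 airway secretory genes. Of 26 gastric and intestinal genes, 6 had more negative effects, among them Tff1 (-7.60) and the galectin gene Lgals4 (-3.62), and 17 when adjusted over the list alone (list adjusted p = 2.26e-09, and adjusted p = 0.0747 with an estimated correlation). Of 26 alveolar type 2 genes, 4 had more negative effects, Sftpa1 (-6.91), Cxcl15 (-5.68), Hc (-5.28) and the surfactant gene Sftpc (-3.69), with 7 when adjusted over the list alone (list adjusted p = 0.0171, and adjusted p = 0.554 with an estimated correlation). Tpsab1 (3.78), the cornified cell adhesion gene Cdsn (3.72), Rasgrf2 (3.65), the lipase gene Lpl (3.41), Ttc7b (3.37) and Nipal2 (2.78) had more positive effects in the double-floxed lines. Airway secretory and Wnt target lists had more negative effects (adjusted p = 0.0197 and 0.0171, and adjusted p = 0.409 for both with an estimated correlation). Squamous and basal, antigen presentation, alveolar type 1 and ciliated lists had more positive effects, with 0 members called (adjusted p = 0.00549, 0.00591, 0.0446 and 0.0456, and adjusted p = 0.409, 0.542, 0.551 and 0.409 with an estimated correlation). The target genes themselves entered this contrast, with Foxa1 at -1.30 (adjusted p = 0.0381) and Foxa2 at -1.96 (adjusted p = 0.0771), since each single-floxed genotype kept 1 of them. In all, 56 of 19085 genes had a more positive and 186 a more negative effect. The count was 0 without the block by line (456 at an unadjusted p under 0.05), 647 with libraries as units and 1151 by DESeq2. It was 150, 136, 109, 114, 95 and 119 without lines 1027B, 1267B, 1526C, 1552A, 1552B and 1552C.

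The effect of losing Foxa1 was also compared with that of losing Foxa2. Of 18384 genes, edgeR called 0 (1071 at an unadjusted p under 0.05, where chance gives 919), and DESeq2 called 145. Foxa2 and Foxa1 had log2 differences of 5.22 and -2.46 (adjusted p = 0.125 and 0.219), so the targeted genes did not pass either. The interferon response list was lower in Foxa1-floxed relative to Foxa2-floxed lines for 20 of 22 genes, with 9 lower when adjusted over the list alone (list adjusted p = 7.40e-14, and adjusted p = 0.258 with an estimated correlation). Foxa2-floxed 4-OHT replicate 2 stood apart in this list, with Irf7 at 326 CPM against 7.84 to 56.0 CPM in the others. Antigen presentation was lower for 11 of 11 genes, with 3 lower when adjusted over the list alone (list adjusted p = 9.66e-07, and adjusted p = 0.3 with an estimated correlation). The gastric and intestinal list had more positive effects in Foxa1-floxed lines for 21 of 26 genes, with 1 higher when adjusted over the list alone (list adjusted p = 0.00145, and adjusted p = 0.539 with an estimated correlation).

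The hairpin experiment asked how Nkx2-1 adds to the effects of Foxa1 and Foxa2 loss. Nkx2-1 stood at 432 ± 0.426 CPM in shScramble and 316 ± 49.4 CPM in shNKX2-1 libraries with vehicle (n = 2 and 2; adjusted p = 0.755), and at 381 ± 35.8 and 191 ± 11.2 CPM with 4-OHT (adjusted p = 0.0763), so the knockdown did not pass the test in either pair. The simulation recovered 5.15% and 3.125% of planted 2-fold changes in these 2 contrasts, so not passing does not show that the knockdown was absent. Foxa2 fell with 4-OHT from 84.0 ± 9.11 to 2.41 ± 0.232 CPM in shScramble and from 76.4 ± 13.4 to 1.11 ± 1.13 CPM in shNKX2-1 libraries (adjusted p = 0.00227 and 0.00175). Foxa1 stood at 27.5 ± 7.34 and 19.2 ± 1.02 CPM in shScramble and at 30.8 ± 4.79 and 20.5 ± 2.25 CPM in shNKX2-1 libraries (adjusted p = 0.469 and 0.236). Foxa3 fell from 17.3 ± 5.76 to 2.27 ± 0.835 and from 22.8 ± 3.59 to 3.26 ± 1.38 CPM (adjusted p = 0.00969 and 0.00973).

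With 4-OHT in shScramble organoids, Tff1 (64.0 ± 55.1 CPM with vehicle), Gkn2 (19.9 ± 2.75 CPM) and Trf (5.19 ± 2.50 CPM) had 0 counts in both 4-OHT libraries, which made them at least 709-fold, 214-fold and 54.1-fold lower. The hepatic and gut transcription factor gene Hnf4a fell from 138 ± 42.4 to 9.52 ± 0.979 CPM (adjusted p = 0.00172). In total 11 of 18 gastric and intestinal genes fell and 0 rose (12 lower when adjusted over the list alone; list adjusted p = 5.86e-12, and adjusted p = 0.0771 with an estimated correlation). Sftpc fell from 881 ± 406 to 9.67 ± 1.11 CPM and Cxcl15 from 696 ± 326 to 19.5 ± 4.81 CPM. However, Chil1, a chitinase-like gene of the same list, rose from 0.278 ± 0.200 to 13.6 ± 0.647 CPM. Of the 23 alveolar type 2 genes, 6 fell and 2 rose (9 and 3 when adjusted over the list alone; list adjusted p = 0.00849, and adjusted p = 0.332 with an estimated correlation). Krt14 rose from 0.312 ± 0.152 to 17.7 ± 2.14 CPM, the tight junction gene Cldn3 from 0.637 ± 0.0325 to 143 ± 18.7 CPM, and the hypoxia-inducible factor gene Epas1 from 0.286 ± 0.0191 to 22.2 ± 1.98 CPM. H60c, a stress ligand for immune receptors, was at least 163-fold higher, from 0 counts to 15.6 ± 1.66 CPM. Of 13 antigen presentation genes, 4 rose and 0 fell (7 higher when adjusted over the list alone), including the MHC class II genes H2-Ab1 and H2-Aa, at least 27.1-fold and 17.6-fold higher to 2.59 ± 0.468 and 1.68 ± 0.462 CPM (list adjusted p = 7.68e-09, and adjusted p = 0.0839 with an estimated correlation). Interferon response genes were higher as a set, with 3 called higher and 2 lower of 19 (list adjusted p = 0.00223, and adjusted p = 0.161 with an estimated correlation). Squamous and basal and cell cycle lists were higher too (adjusted p = 0.00849 and 0.00614, and adjusted p = 0.229 and 0.747 with an estimated correlation). Wnt target, lipid synthesis and unfolded protein response lists were lower (adjusted p = 0.00496, 0.00849 and 0.0163, and adjusted p = 0.332, 0.604 and 0.720 with an estimated correlation). Chromosomes 8 and 19 (781 and 516 genes) had median log2 changes of -0.303 and -0.272. They held 33 and 26 lower calls and 4 and 9 higher calls. The SD of chromosome medians was 0.122, and 0.120 after the trend with GC content and transcript length was removed. The cause was not tested, so the lower calls need not all follow from loss of Foxa1 and Foxa2. Over all chromosomes, the edgeR test called 241 genes higher and 386 lower of 14465. The count was 138 and 170 without 4-OHT replicates 2 and 1, and 243 and 176 without vehicle replicates 1 and 2. It was 1651 and 1655 without shNKX2-1 4-OHT replicates 1 and 2, and 1092 by DESeq2.

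With 4-OHT in shNKX2-1 organoids, Trf fell from 988 ± 300 to 0.367 ± 0.0365 CPM, Muc5b from 1849 ± 598 to 25 ± 16.1 CPM, Muc5ac, the main gastric mucin, from 458 ± 73.7 to 6.18 ± 2.94 CPM, and the surfactant gene Sftpb from 3953 ± 2010 to 166 ± 97.1 CPM (adjusted p = 7.44e-04, 0.00124, 0.00109 and 0.00309). Ttr, Scgb3a1 and the antimicrobial lectin gene Reg3g had 0 counts with 4-OHT, at least 526-fold, 276-fold and 298-fold lower. Of 18 gastric and intestinal genes, 12 fell and 0 rose (13 lower and 2 higher when adjusted over the list alone; list adjusted p = 5.14e-09, and adjusted p = 0.0717 with an estimated correlation). Of 23 alveolar type 2 genes, 8 fell and 2 rose (12 and 3 when adjusted over the list alone; list adjusted p = 9.01e-05, and adjusted p = 0.165 with an estimated correlation). Ivl rose from 33.0 ± 7.75 to 151 ± 12.2 CPM and the lipase gene Lipk from 0.560 ± 0.274 to 35.2 ± 3.80 CPM. Of 19 interferon response genes, 7 rose and 0 fell (12 higher when adjusted over the list alone), including the viral RNA sensor Ddx58 (12.6 ± 0.0127 to 53.8 ± 4.25 CPM; list adjusted p = 2.78e-06, and adjusted p = 0.0717 with an estimated correlation). Antigen presentation rose for 4 of 13 genes and fell for 0 (list adjusted p = 3.10e-05, and adjusted p = 0.151 with an estimated correlation). Airway secretory genes fell for 5 of 14 (list adjusted p = 0.00593, and adjusted p = 0.165 with an estimated correlation). Squamous and basal, cell cycle, and NF-kB and chemokine lists were higher (adjusted p = 0.00593, 0.0239 and 0.0444, and adjusted p = 0.165, 0.891 and 0.834 with an estimated correlation). The hypoxia and glycolysis list was lower (adjusted p = 0.00593, and adjusted p = 0.834 with an estimated correlation). There were 394 genes called higher and 525 lower, of which 137 and 265 were shared with shScramble (6.56 and 14 by chance) and 0 had opposite calls. Chance here takes genes as independent, but chromosomes 8 and 19 shifted down in both contrasts (medians -0.174 and -0.468 in shNKX2-1). Chromosome 19 held 9 higher and 37 lower calls. Chromosome 3 held 54 higher and 13 lower calls, with a median log2 change of 0.42. The cause was not tested, so these calls need not all follow from loss of Foxa1 and Foxa2. Replicate 2 of the 4-OHT group, with 11.7% mitochondrial counts, stood apart from replicate 1, and the fitted changes followed GC content (r = -0.273 across genes, which are not independent replicates). The count was 1041 without it, 6946 without replicate 1, and 279 and 258 without vehicle replicates 1 and 2. It was 588 and 581 without shScramble vehicle replicates 1 and 2, 510 without either shScramble 4-OHT replicate, and 1786 by DESeq2.

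Between hairpins in vehicle, 30 genes were called higher and 4 lower in shNKX2-1 libraries. Trf stood at 5.19 ± 2.50 CPM in shScramble and 988 ± 300 CPM in shNKX2-1, Dmbt1, a mucosal defence gene, at 1.5 ± 0.677 and 252 ± 72.6 CPM, and Itih4 at 0.260 ± 0.114 and 52.2 ± 30.1 CPM (adjusted p = 0.00442, 0.00442 and 0.0112). The calcium channel gene Trpv6 had 0 counts in shScramble and was at least 291-fold higher, at 28.0 ± 1.86 CPM. The growth factor gene Fgf2 was lower, at 386 ± 48.2 and 69.1 ± 6.05 CPM, as was Arhgap29 (44.8 ± 10.1 and 7.02 ± 0.287 CPM). Of 14 airway secretory genes, Scgb3a1 was called higher, with 2 counts in shScramble and a ratio of 131 to 3918 (95% counting interval), and 6 were higher and 1 lower when adjusted over the list alone (list adjusted p = 1.54e-05, and adjusted p = 0.237 with an estimated correlation). No member of the other lists was called. The cell cycle list was lower for 30 of 30 genes (list adjusted p = 7.50e-05, and adjusted p = 0.640 with an estimated correlation) and the alveolar type 1 list for 16 of 19 (list adjusted p = 2.03e-04, and adjusted p = 0.540 with an estimated correlation). Alveolar type 2, lipid synthesis, interferon response and MAPK feedback lists were lower too (adjusted p = 0.00459, 0.00459, 0.0111 and 0.0398, and adjusted p = 0.505, 0.542, 0.310 and 0.540 with an estimated correlation). Gastric and intestinal genes were higher for 16 of 18 members (list adjusted p = 0.00238, and adjusted p = 0.310 with an estimated correlation), as were Wnt targets for 7 of 9 (list adjusted p = 0.0280, and adjusted p = 0.540 with an estimated correlation). Chromosome 3 genes had a median log2 difference of -0.31, the widest of any chromosome, and chromosome 8 genes had one of -0.22. The SD of chromosome medians was 0.0977, and 0.0975 after the trend with GC content and transcript length was removed. The cause was not tested, so the differences between hairpins in vehicle need not all follow from knockdown of Nkx2-1. The count of 34 became 0 without shScramble vehicle replicate 1 or 2 (794 and 844 at an unadjusted p under 0.05). It became 8 and 13 without shNKX2-1 vehicle replicates 1 and 2, 22 without shScramble 4-OHT replicate 1, 275 and 271 without shNKX2-1 4-OHT replicates 1 and 2, and 284 by DESeq2.

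Between hairpins in 4-OHT, 140 genes were higher and 88 lower in shNKX2-1 libraries. That group holds replicate 2, with 11.7% mitochondrial counts, and the fitted changes followed GC content (r = -0.313 across genes, which are not independent replicates). The SD of chromosome medians was 0.131, and 0.0638 after the trend with GC content and transcript length was removed. Alveolar genes were among those lower: Sftpb at 2311 ± 109 and 166 ± 97.1 CPM, the aspartic protease gene Napsa at 33.2 ± 3.10 and 0.449 ± 0.524 CPM, and Ager, a receptor of alveolar type 1 cells, at 436 ± 4.5 and 9.83 ± 10.5 CPM (adjusted p = 0.0176, 0.00755 and 0.0223). Of 23 alveolar type 2 genes, 5 were lower and 2 higher (9 and 3 when adjusted over the list alone), the higher ones being Chil1 and the lysosomal protease gene Ctsh (list adjusted p = 0.00125, and adjusted p = 0.716 with an estimated correlation). Of 19 alveolar type 1 genes, Ager, Clic5 and Hopx were lower (8 lower and 2 higher when adjusted over the list alone; list adjusted p = 0.00125, and adjusted p = 0.716 with an estimated correlation). Krt14 (17.7 ± 2.14 and 0.890 ± 0.480 CPM), Tpsab1 (32.7 ± 6.47 and 0.523 ± 0.517 CPM) and Hdc, the enzyme that makes histamine (82.6 ± 21.9 and 3.97 ± 2.50 CPM), were lower too. Krt4 stood at 0.247 ± 0.167 and 13.9 ± 5.21 CPM and the iron-binding gene Lcn2 at 189 ± 96.2 and 2000 ± 1448 CPM, both called higher. The cell cycle list was lower with 0 of 30 genes called (list adjusted p = 0.00481, and adjusted p = 0.716 with an estimated correlation). The count of 228 was 336 without shNKX2-1 4-OHT replicate 2, 5758 without replicate 1, 19 and 0 without shScramble 4-OHT replicates 1 and 2 (923 at an unadjusted p under 0.05 for the latter). It became 86 and 69 without shScramble vehicle replicates 1 and 2, 127 and 129 without shNKX2-1 vehicle replicates 1 and 2, and 704 by DESeq2.

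Whether the 4-OHT effect differed between hairpins was tested as an interaction. The edgeR test called 0 of 14465 genes (782 at an unadjusted p under 0.05, where chance gives 723) and DESeq2 called 89, at a size where the simulation recovered 19.2% of planted 4-fold changes. This contrast includes shNKX2-1 4-OHT replicate 2, with 11.7% mitochondrial counts, and its fitted values followed GC content (r = -0.322 across genes, which are not independent replicates). Interferon response genes had more positive 4-OHT effects in shNKX2-1 for 15 of 19 members, with 1 called when adjusted over the list alone (list adjusted p = 0.00378, and adjusted p = 0.425 with an estimated correlation). Alveolar type 2 genes had more negative effects for 17 of 23 members, with 1 higher and 3 lower when adjusted over the list alone (list adjusted p = 0.0488, and adjusted p = 0.677 with an estimated correlation). The count was 3552 without shNKX2-1 4-OHT replicate 1 and 7 without replicate 2. The genes called in double-floxed organoids were followed in the hairpin experiment as well. With 4-OHT in shScramble, 41 of 259 called higher and 99 of 264 called lower had the same call (4.43 and 7.27 by chance; camera p = 1.57e-30 and 5.89e-53, and p = 0.0276 and 8.49e-04 with an estimated correlation). In shNKX2-1 the same calls numbered 65 of 259 and 129 of 264, and the higher list did not pass with an estimated correlation (7.22 and 9.92 by chance; camera p = 9.49e-18 and 8.44e-44, and p = 0.0648 and 0.00124 with an estimated correlation). Between hairpins in vehicle, the genes called lower in double-floxed organoids lay higher in shNKX2-1 libraries (camera p = 3.02e-04), but not past the threshold with an estimated correlation (p = 0.102) or with lists from lines other than 1027B (p = 0.403). Between hairpins in 4-OHT neither list passed (camera p = 0.959 for genes called higher and 0.693 for genes called lower, at the preset correlation).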

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

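The tests of mast cell marker genes, of Foxa2 recombination and of splits with a block of line and run were chosen only after the result was seen, and the other comparisons with splits of the libraries were set out before. Of 206 groups of 4 to 10 libraries checked for a library far from the others (Dixon's test at 95%), 33 had one, while chance gives about 1 in 20.

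In double-floxed vehicle libraries, replicate 3 (line 1292B) stood above the others for Prl2c3 (6.63 CPM), Fgf15 (3.18), Lypd5 (3.98), Ctla2a (9.23), Tppp3 (6.90), Ccdc80 (55.2) and Csf1r (1.54 CPM). The same line's 4-OHT library, replicate 3, stood above for Prl2c3 (1359 CPM), Pglyrp3 (23), Fgf15 (113), Ctla2a (241), Tppp3 (48.4) and Ccdc80 (16.4 CPM). Vehicle replicate 5 (line 1027D) held the only Rnf144a and Col6a1 reads of its group (0.178 CPM each) and the highest Rsad2 (1.43) and Cpa4 (2.41 CPM). The 4-OHT replicate 5 was highest for Trf (1.15 CPM), Sftpa1 (1.68), Myh6 and Serpind1 (0.0294 CPM each). In line 1027B, vehicle replicate 1 stood apart for Pgc (177 CPM) and Cxcl15 (2473 CPM), vehicle replicate 4 for Csf1 (32.1 CPM) and for depth (29.5 M counts). In the same line, 4-OHT replicate 4 stood apart for Foxa3 (16.1 CPM) and Vsig1 (5.35 CPM), and 4-OHT replicate 1 stood apart for its mitochondrial share (2.61%).

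In Foxa2-floxed organoids, replicate 2 (line 1267B) stood above the others. Its vehicle library held 47.5 CPM of Irf7 and 3.81 CPM of Csf2, and its 4-OHT library held 326 CPM of Irf7, 7.29 CPM of Zbp1 and 649 CPM of B2m.

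The effect of 4-OHT in double-floxed lines differed from the mean effect in the single-floxed genotypes, by the test of the difference itself, for 242 genes. A gene that responds to Foxa2 alone can also pass this test. The log2 differences were 3.78 for Tpsab1, 3.72 for Cdsn, 3.65 for Rasgrf2, 3.41 for Lpl, 3.37 for Ttc7b and 2.78 for Nipal2. They were -9.29 for Trf, -9.19 for Ttr, -8.96 for Gkn2, -8.61 for Gkn3, -8.55 for Scgb3a1 and -8.31 for Myh6.

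Summed mast cell protease CPM was on average higher after 4-OHT in each organoid line, but in line 1027B it fell from 207 to 107 CPM between replicates 1 and rose from 546 to 1196 CPM between replicates 4. Cells of the mast or basophil lineage would bring their other abundant transcripts, but the lineage genes summed to a median of 0.931% of the protease CPM over the 9 double-floxed and Foxa2-floxed 4-OHT libraries (0.244% to 21.1%, the highest in line 1267B), which argues against such cells as the source. Recombination of Foxa2 is a candidate explanation that stays open: log2 ratios of summed protease CPM ran from 0.79 to 2.84 in the 5 lines with floxed Foxa2 and from 0.42 to 1.65 in the 3 without. A one-sided exact permutation test over the 56 splits of lines gave p = 0.0893. The 3 lines without floxed Foxa2 share a line number and a sequencing run, so they may not be the independent units that the test assumes. Reads shared between protease paralogs were not tested.

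The counts of changed genes were compared with those from other splits of the libraries. These splits treat repeat libraries of a line as separate units. A wrong split also leaves the treatment effect in the spread, which lowers its calls. The splits therefore cannot measure chance between tumours. For double-floxed organoids, 1 of 100 splits drawn from 126, the real one, gave as many as 592 genes, and the highest of the others gave 1. For Foxa1-floxed organoids, 2 of 100 splits gave as many as the 2 genes of the real one, and the highest of the others gave 2. For Foxa2-floxed organoids, 2 of 34 splits gave as many as 580, so the splits alone do not exclude chance, and the highest of the others gave 807. That split grouped line 1267B by sequencing run (17699 against 17992) but kept 1526C grouped by treatment, so it still held the treatment effect in that line. With a block of line and run, 914 genes were called for the real split. There 3 of 34 splits gave as many, but the 2 others, at 938, measured only the treatment effect in 1526C, so this comparison decides nothing about chance. Chance as the cause of the whole count is argued against by the calls shared with the double-floxed lines, 77 higher and 85 lower where chance gives 5.21 and 4.47, with 0 opposite.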

How the results depend on the processing

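All alternatives were fixed before the data were examined. Of the recomputed counts of changed genes, 45 stayed within 1.5 times of the reported one, and 88 did not. In tests of named genes, 2996 kept their side of the threshold, 907 lost their call, 26 gained one and 0 reversed. The cause of the changes was not tested, except that fewer lines or libraries leave fewer degrees of freedom.

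For double-floxed organoids (592 genes) the count was 1892 by DESeq2, 2391 with no filter on low counts, 82 with no replicate block, and 1783 with a block of line and run. It was 111, 0 (1660 at an unadjusted p under 0.05 by edgeR) and 253 without lines 1027B, 1027D and 1292B. For Foxa1-floxed organoids (2 genes) it was 246, 1141 and 1 under the first 3 of these, 0 with counts summed per line (1516 unadjusted), and 1, 21 and 1 without lines 1552A, 1552B and 1552C. For Foxa2-floxed organoids (580 genes) it was 988, 1816, 5 and 914 under the first 4, 73 with counts summed per line, and 133 with this genotype alone. It was 1059 and 16 without lines 1267B and 1526C. For the double-floxed against single-floxed effects (242 genes) it was 1151, 507 and 0 under the first 3 (456 unadjusted for the last), and 647 with libraries as units. It was 150, 136, 109, 114, 95 and 119 without lines 1027B, 1267B, 1526C, 1552A, 1552B and 1552C. For the Foxa1 against Foxa2 effects (0 genes, 1071 unadjusted) it was 145 by DESeq2, 58 with no filter, 45 with libraries as units and 5 without line 1267B. DESeq2 and no filter gave 284 and 461 between hairpins in vehicle, 704 and 1058 between hairpins in 4-OHT, 1092 and 1372 with 4-OHT in shScramble, 1786 and 2455 with 4-OHT in shNKX2-1, and 89 and 227 for the interaction.

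Leaving out 1 library gave 228 to 575 genes in double-floxed and 227 to 927 in Foxa2-floxed organoids. In the hairpin fit, where the lone library left in a group is assumed to vary like the other groups, it gave 0 to 275 between hairpins in vehicle, 0 to 5758 between hairpins in 4-OHT, 138 to 1655 with 4-OHT in shScramble, 258 to 6946 with 4-OHT in shNKX2-1 and 0 to 3552 for the interaction. The lows of 0 by edgeR had 794, 923 and 699 genes at an unadjusted p under 0.05. The upper ends came from leaving out replicate 1 of shNKX2-1 4-OHT, or replicate 2 for 1655.

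With an estimated correlation, 75 of 224 list tests lost their call and 0 reversed. Leaving out a line changed 22 of 188, with 1 reversal, where the cell cycle list went from up (adjusted p = 0.893) to down without line 1027D (adjusted p = 5.99e-07). Genes called in double-floxed organoids, followed as lists, no longer passed for the higher list with 4-OHT in shNKX2-1 with an estimated correlation (p = 0.0648), for the lower list between hairpins in vehicle (p = 0.102 with an estimated correlation, p = 0.403 with lists from lines other than 1027B) and for the lower list in the interaction (camera p = 0.0126, then p = 0.219 and 0.289). Depth limits genes at a few counts per library, of which folds against 0 counts are bounds.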

Other observations

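Tests of shNKX2-1 4-OHT replicate 2 against chromosome changes and against a few abundant genes were chosen after the result was seen; its tests for GC content and for another line, and both tests of the runs of line 1027B, were set out before.

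Several programmes beyond lineage identity moved with 4-OHT as sets under the preset correlation. In double-floxed organoids the unfolded protein response list was lower (adjusted p = 0.00286, and adjusted p = 0.396 with an estimated correlation), with Pdia4, an endoplasmic reticulum chaperone, the only call of 14 genes at 302 ± 42.6 and 195 ± 37.7 CPM. Antigen presentation was higher with 0 of 13 genes called (adjusted p = 0.00153, and adjusted p = 0.457 with an estimated correlation). Wnt targets were lower (adjusted p = 0.0317, and adjusted p = 0.328 with an estimated correlation) with Sp5 as the call, and so were hypoxia and glycolysis genes (adjusted p = 0.0300, and adjusted p = 0.575 with an estimated correlation) and embryonic lung tip genes (adjusted p = 0.0115, and adjusted p = 0.396 with an estimated correlation) with Foxp2 as the call. The NF-kB and chemokine list held Csf1, which rose, and the adhesion gene Icam1, which fell from 259 ± 113 to 46.2 ± 31.1 CPM, and did not pass as a set (adjusted p = 0.284). Neither did the airway secretory (0.113), alveolar type 1 (0.284), transitional alveolar (0.893), mesenchymal transition (0.892), epithelial junction (0.326), cell cycle (0.893), MAPK feedback (0.893), YAP and TEAD target (0.687) and lipid synthesis (0.107) lists. The median and the test differed in sign for the transitional alveolar and mesenchymal transition lists. The neuroendocrine list had under 3 measured genes in double-floxed organoids and did not pass in Foxa1-floxed or Foxa2-floxed organoids (adjusted p = 0.147 and 0.993, the latter with a median and mean of opposite sign).

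In Foxa2-floxed organoids the NF-kB and chemokine and transitional alveolar lists were higher (adjusted p = 2.32e-05 and 0.00259, and adjusted p = 0.273 for both with an estimated correlation). Unfolded protein response, lipid synthesis, and hypoxia and glycolysis lists were lower (adjusted p = 5.14e-04, 0.00259 and 0.0113, and adjusted p = 0.317, 0.524 and 0.596 with an estimated correlation). Krt7, a keratin of simple epithelia, rose from 1465 ± 226 to 2534 ± 443 CPM and the cell cycle regulator Ccnd1 from 466 ± 84.7 to 769 ± 232 CPM. The splicing factor gene Esrp1 fell from 219 ± 21.2 to 177 ± 11 CPM and Icam1 from 107 ± 99.0 to 47.9 ± 31.4 CPM, while the cytokine gene Csf2 rose from 1.37 ± 1.63 to 6.84 ± 6.57 CPM. In shNKX2-1 organoids with 4-OHT, Sp5 went from 19.5 ± 2.08 CPM to 0 counts, at least 179-fold lower, and the membrane scaffold gene Cav1 rose from 66.8 ± 36.1 to 245 ± 61.2 CPM.

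Replicate 2 of shNKX2-1 4-OHT differed from replicate 1 with an SD of log2 ratios of 1.02, against 0.412 to 0.587 in the other replicate pairs. Its ratios followed GC content (r = -0.618 across genes, which are not independent replicates), and removing the trend with GC content and transcript length, which took 42.0% of the variance, brought the SD to 0.780, or 1.33 times the next pair, in line with a bias of that kind. The SD of chromosome medians fell from 0.230 to 0.0482 after the trend was removed, so most of that spread went with the trend. The remainder lay close to the highest of the random assignments (0.0486) and above the highest other pair (0.0417). Removing the trend can also take out chromosome differences that go with GC content, so chromosome changes stay open. Another line under the label is argued against by r = 0.679 to line 1027B and 0.191 to the next. A few genes taking most of the counts stay open, because leaving out mitochondrial and the 10 most abundant genes (ratio 1.74) moved the SD of no pair by 1% and so decides nothing. A biological difference between the 2 cultures was not tested and stays open too.

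In line 1027B the alveolar type 2 genes differed between sequencing runs, with a median log2 difference of -2.05 in vehicle (22 of 24 genes lower in run 17992), and Sftpc at 866 and 4.93 CPM. With 4-OHT it was -0.50 (16 of 24 lower). A batch difference shared by the runs is argued against by line 1027D, whose median was 0.0937 in vehicle and 0.89 with 4-OHT. Another organoid line under the label is argued against by r = 0.751 between the runs' vehicle libraries, against 0.405 to the next line. A change in the culture between the runs stays open and was not tested.

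Chromosome medians spread more than under random assignment in all 10 comparisons. The widest were a median log2 of -0.31 on chromosome 3 between hairpins in vehicle, -0.30 on chromosome 8 with 4-OHT in shScramble, -0.47 on chromosome 19 with 4-OHT in shNKX2-1 and 0.44 on chromosome 3 in the interaction. The last 2 followed GC content (r = -0.273 and -0.322 across genes, which are not independent replicates). After the trend with GC content and transcript length was removed, their SD of chromosome medians fell from 0.206 to 0.126 and from 0.178 to 0.117, with the widest on chromosome 3 in both (0.34 and 0.29).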
